A study of Homo sapiens with 12 samples.

How the data were processed

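The assay was ac4C-RIP-seq, in which RNA fragments are captured with an antibody to N4-acetylcytidine (ac4C), a modified cytidine that the RNA acetyltransferase NAT10 writes, and are then sequenced. The cells were H1, an established human embryonic stem cell line. Wild-type cells were compared with cells carrying a NAT10 short hairpin RNA, delivered by lentivirus with GFP. Per the labels, the transduced cells were cultured for 48 hours, and GFP-positive cells were then enriched and grown with 0.5 ug per ml puromycin. The labels call the other group wild type and name no control hairpin. Per the labels' protocols, ribosomal RNA was removed, RNA was broken into fragments of about 200 nt, and a directional library kit was used. The labels also give the molecule as poly(A) RNA, and which RNA entered the assay is not settled here.

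The series has 12 samples: 2 libraries each of immunoprecipitate, input and IgG control from wild-type and knockdown cells. The 4 peak lists analysed here carry the names of the 4 immunoprecipitation libraries, 1 list per library, so peaks were not pooled over replicates. The input and IgG libraries were not analysed here, so a peak cannot be set against the amount of its RNA. Per the submitters' processing notes, fastp 0.21.1, HISAT2 2.2.1, SAMtools 1.12 and bedtools 2.30.0 were used with build hg38. The peak caller, its threshold, its control library and the gene annotation are not given in the sources used here.

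Each deposited list gives a peak's chromosome, start, end, number, score, strand, Ensembl gene identifier and gene symbol. The score is the authors', and its meaning is not stated. No score was below 10, finite scores ended at 308.209, and between 1 and 24 scores per list were infinite, a range that the -log10 of a p-value would have. It was used only to rank peaks within a list, as a percentile. Starts in the deposited lists count from 0 and are given here from 1. Widths were multiples of 25 nt for 64.5 to 69.9% of peaks. Between 22.8 and 25.3% of peaks spanned over 1000 nt, and the longest span was 766068 nt, so a span can hold introns. Read depth is unknown, since the lists hold no read counts. The intervals on shares of peaks are exact (Clopper-Pearson) at the 95% level and cover counting error only.

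Peak numbers ran above the number of peaks in each list. The numbers that no listed peak carried came to 6048 and 6713 in the wild-type lists and 7213 and 8564 in the knockdown lists. The numbering followed the Ensembl identifier of the gene, and 96.0 to 96.5% of peaks stood in that order. The place of any gene or region in a list that lacked it could therefore be found, and the numbers absent at that place were counted. Such a number is called an unlisted number here. It marks a peak that was numbered and is not in the list, and it can belong to the gene itself or to a neighbour in the order of identifiers. Places with 1 lost or gained gene were compared, after the data were seen, with places of 1 other gene that the list lacked and 2 lists held.

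Peaks of the 4 lists were merged into regions where they overlapped by at least 1 bp on the same strand. A region or gene was called lost if both wild-type lists and neither knockdown list held a peak in it, gained in the opposite case, and kept if all 4 lists held one. The same counts were made for the other splits of the 4 lists into pairs. These splits cannot give a p-value under 0.05, so no p-value is attached to the counts. Values per library were compared by a two-sided exact permutation test over the 6 arrangements of 2 against 2, whose smallest possible p is 0.333. Nothing in the labels says that the replicates were separate cultures, so the p-values of this test measure only the spread between these samples, which may be technical.

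Gene lists were tested by a two-sided Fisher's exact test. For lost genes the background was genes with a peak in both wild-type lists, for gained genes those with a peak in both knockdown lists, and for kept genes those with a peak in any list. Benjamini-Hochberg adjustment ran over the lists with at least 5 members in the background, and the threshold was an adjusted p of 0.05. Genes are not replicates, so these tests describe the 4 lists. The 25 lists covered ac4C and RNA modification enzymes, pluripotency, markers of ectoderm, mesoderm, endoderm and trophectoderm, histone chaperones, Polycomb and COMPASS, chromatin remodellers, histone acetylation and methylation enzymes, and histone genes. They also covered ribosomal proteins, translation factors, ribosome biogenesis, mitochondrial-encoded genes, nuclear-encoded oxidative phosphorylation, glycolysis, cell cycle, splicing, chaperones and proteasome, TGF-beta, FGF and WNT signalling, cytoskeleton, adhesion and matrix, noncoding RNAs, p53 targets and apoptosis, and zinc finger proteins. Lists filled by symbol prefix also caught some pseudogenes and an antisense RNA.

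Named genes followed a rule. It took NAT10, the 10 lost, 10 gained and 10 kept regions whose lowest within-list score percentile was highest, with 1 region per gene, and from each gene list up to 4 lost, 2 gained and 4 kept members ranked in the same way. The comparisons, gene lists, tests, naming rule and most alternatives were chosen before the data were examined.

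Positions within genes were taken from a RefSeq gene table of assembly GRCh38.p14, to which 10919 of 10992 gene identifiers (99.3%) matched by symbol and chromosome. A peak's position was its midpoint along the genomic span of its gene. No genome sequence or exon annotation was used here, so a planned division of peaks into untranslated, coding and intronic parts and a planned count of bases and motifs were not run. The share of peaks per chromosome, per 10% of the gene span and by gene length were added after the data were seen. Gene lengths of the classes were compared by a permutation test of the difference of median log2 span with 100000 permutations.

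Alternatives were a stricter overlap, a 200 nt gap, the stronger 50% of each list, equal list lengths, strand ignored, nuclear chromosomes only, the replicate number as a block, each library left out in turn, genes with 1 region only, and logistic regression with score percentile and number of regions. Merging within genes only, spans up to 1000 nt only, and leaving out regions with unlisted numbers were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for plots.

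The code was tested on simulated data. Of 6000 lost, 5000 gained and 3000 kept regions planted among 54000, 100% were recovered in their class and 0 others were called. Planted peaks of a region always overlapped and were never missing from a list of their class, unlike the peaks of the real lists. That result checks the code and not how well the classes are recovered in these data. Where 60% of lost and of gained regions were planted with no unlisted number, 42.5% and 44.7% were counted as such, because numbers left out of neighbouring regions were also counted. Counts of regions with no unlisted number are therefore too low. For the lost genes, lists of 40 members among 5600 genes were planted with 40% of members lost against 13% of other genes. Over 100 draws, 92.4% of them were called, as were 0.8% of lists with no planted difference.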

Results

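Regions of RNA enriched with an antibody to N4-acetylcytidine (ac4C) were compared between wild-type H1 human embryonic stem cells and H1 cells in which NAT10, the enzyme that acetylates cytidine in RNA, was knocked down with a short hairpin RNA. The comparison asks where ac4C peaks depend on NAT10. The labels give transduction, GFP enrichment and puromycin for the knockdown cells only, so effects of these cannot be told apart from that of NAT10. Each genotype had 2 immunoprecipitation libraries, and each library had its own peak list. The wild-type lists held 37988 and 38150 peaks and the knockdown lists 27787 and 36476. Read depth is unknown. The score attached to each peak is the authors', and it ranks peaks only within a list. Coordinates are those of build hg38, counted from 1.

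NAT10 itself (ENSG00000135372) carried 7 and 9 peaks in the wild-type lists, spread over chromosome 11 from 34107308 to 34146537, and 0 in either knockdown list. Its highest scores were 22.4 and 22.7 in the wild-type lists, at percentiles 90.1 and 81.2. The lists thus separate the libraries labelled wild type from those labelled knockdown at the targeted gene. A peak list gives no level of NAT10 RNA, and 3 and 4 unlisted numbers, which mark peaks that were numbered and left out of the list, stood at its place in the knockdown lists.

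**Figure D1:**
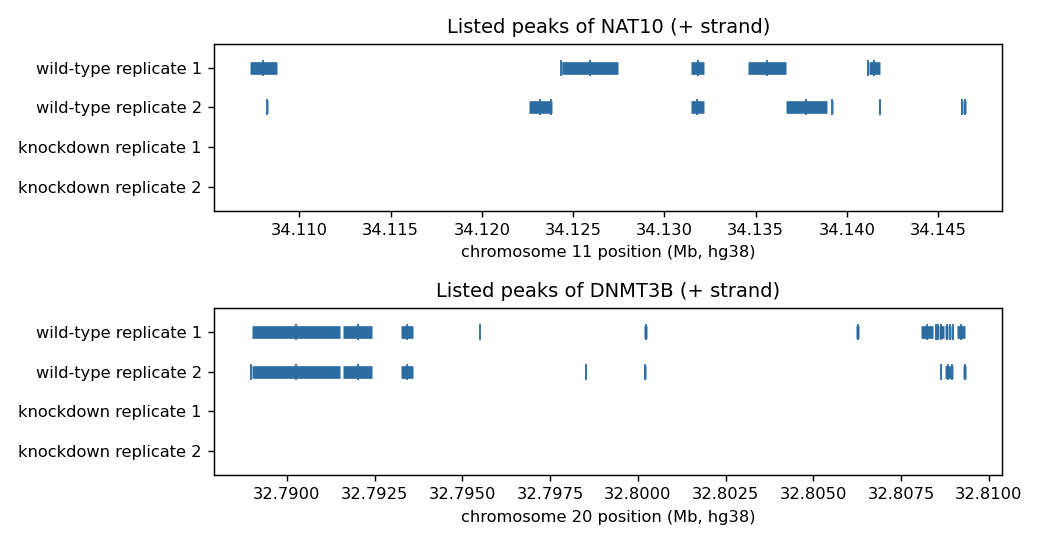
Listed peaks of NAT10 (chromosome 11) and DNMT3B (chromosome 20) in each of the 4 libraries, drawn to scale as blocks against the hg38 position in Mb. Thin ticks mark block midpoints, and the knockdown tracks are empty while the wild-type tracks hold 7 and 9 peaks at NAT10 and 14 and 10 at DNMT3B.

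Peaks lay almost wholly in protein-coding genes, which held 96.0 to 96.3% of the peaks whose gene was matched. Peaks on mitochondrial RNA numbered 22 and 23 in the wild-type lists and 7 and 8 in the knockdown lists. Genes with a peak numbered 6926 and 7365 in wild type and 6930 and 7872 in knockdown, with 5.48 and 5.18 peaks per gene against 4.01 and 4.63. The number of peaks was 38069 ± 115 in wild type and 32131.5 ± 6144 in knockdown (SD, n = 2 each), a ratio of 0.844 (exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). The difference rested on 1 knockdown library, and it went the other way for genes with a peak (ratio 1.04, exact permutation p = 0.667) and for covered length (73.8 and 78.4 against 68.8 and 93.6 Mb, ratio 1.07, exact permutation p = 1).

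Libraries of the same genotype shared more peaks than libraries of different genotypes. On average, 36.8% of peaks in a wild-type list overlapped a peak of the other wild-type list, and 43.1% did so between the knockdown lists, while the 4 pairs across genotypes lay between 23.3 and 24.4%. The same order held for covered bases, with Jaccard indices of 0.197 and 0.324 within genotypes and 0.136 to 0.143 between them. Covered length and covered bases weigh long spans most, which can hold introns, and overlap was not measured with a limit on span. Genes shared within a genotype numbered 5607 and 5612, against 4645 to 5365 between genotypes.

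Single regions of strongly scored RNA separated the genotypes. The lost regions, with a peak in both wild-type lists and in neither knockdown list, were led by RPL31, a protein of the large ribosomal subunit (chromosome 2, 101005953 to 101006077, plus strand), and by DNMT3B, a de novo DNA methyltransferase (chromosome 20, 32793256 to 32793603, plus strand). They were followed by TERF1, a protein that binds telomeric repeats (chromosome 8, 73032037 to 73038708, plus strand), the mitochondrial tRNA gene MT-TE (14674 to 14742, minus strand) and RPL29 (chromosome 3, 51995042 to 51995116, minus strand). Further leading lost regions lay in ATP5MJ, YBX3 and C12orf73 and in the mitochondrial tRNA gene MT-TP. In each of these regions the peak stood at percentile 99.8 or higher of both wild-type lists. Loss of a region did not always mean loss of the gene: RPL31 kept 3 and 8 peaks elsewhere in the knockdown lists, and TERF1 13 and 9, whereas DNMT3B, RPL29, YBX3 and C12orf73 had 0 in both. DNMT3B carried 14 and 10 peaks in the wild-type lists and YBX3, an RNA-binding cold-shock protein, 16 and 10. Unlisted numbers stood at the place of each of these regions in both knockdown lists, with 11 and 15 at DNMT3B, 13 and 10 at YBX3 and 1 and 1 at MT-TE.

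The gained regions, with a peak in both knockdown lists and in neither wild-type list, were led by the histone genes H2BC4 (chromosome 6, 26115123 to 26123926, minus strand) and H4-16 (chromosome 12, 14770728 to 14771127, minus strand), and by MT-TT, a mitochondrial tRNA gene (15888 to 15953, plus strand). All 3 had an infinite score in both knockdown lists. They were followed by SLIRP, which binds mitochondrial mRNA (chromosome 14, 77710817 to 77711760, plus strand), MFAP2, a microfibril protein, and the histone gene H2BC14. NAP1L1, a histone chaperone, had 9 and 13 peaks in the knockdown lists and 0 in the wild-type lists, and its leading region lay at 76068902 to 76073811 of chromosome 12 (minus strand). ST13, a cochaperone of HSP70, RAN, the GTPase of nuclear transport, and CCT5, a chaperonin subunit, gained a region while holding other peaks in all 4 lists. SLIRP and MFAP2 likewise had peaks elsewhere in both wild-type lists, 3 and 4 in SLIRP and 2 and 2 in MFAP2. Unlisted numbers stood at 8 of these 10 places in the wild-type lists, up to 24 and 14 at NAP1L1. None stood at H4-16 or MFAP2. Ribosomal protein, histone and mitochondrial tRNA genes have near-identical copies in the genome, so the origin of their reads is uncertain.

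Regions kept in all 4 lists were led by the mitochondrial tRNA genes MT-TI (4263 to 4331, plus strand) and MT-TW (5512 to 5579, plus strand), and then by PTCD1, which acts in mitochondrial RNA metabolism (chromosome 7, 99460077 to 99460201, minus strand). SAE1, a subunit of the SUMO-activating enzyme, CALD1, RUFY2, CCZ1, TCEA1 and the histone gene H2BC5 also held one. TERF1 held both a kept region (chromosome 8, 73030312 to 73030411) and the lost one named above, so peaks of 1 gene differed in class.

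In all, 89916 regions were formed, of which 62092 had a peak in 1 list only. Of the 12697 regions shared by both wild-type lists, 6631 (52.2%) were lost, and of the 12137 shared by both knockdown lists, 5838 (48.1%) were gained. Only 3054 regions were kept. Among these 89916 regions, independent lists of these sizes would give 6199 lost and 3522 gained regions. Regions that no list held are left out of that calculation, so it is no measure of chance over all transcripts. Lost and gained regions together came to 12469, against 3016 and 3028 for the other splits of the 4 lists into pairs. No unlisted number stood at the place of 2441 of the lost regions (36.8%) and 1935 of the gained ones (33.1%), against 40.5 to 45.0% in the other splits, and their sum of 4376 compared with 1274 and 1311 there. The counts depend on holding a peak in both lists of a genotype: lost regions numbered 26024 without wild-type replicate 1 and 25813 without wild-type replicate 2, gained regions 23202 and 16909 without knockdown replicate 1 and 2, and kept regions 4607 without wild-type replicate 1 and 4783 without knockdown replicate 1. Taking the stronger 50% of each list gave 3260 lost, 3226 gained and 926 kept regions.

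**Figure D2:**
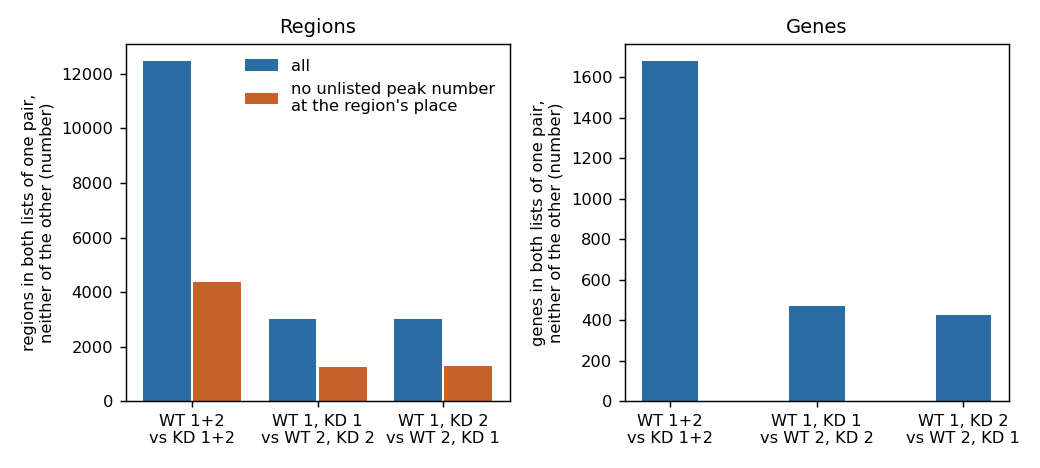
Number of regions (left) and genes (right) with a peak in both lists of one pair and in neither list of the other, for the split by genotype and the other splits of the 4 lists (WT, wild type; KD, knockdown). Blue bars are all regions or genes and orange bars are regions with no unlisted number at their place; the split by genotype holds 12469 regions and 1679 genes, above both other splits.

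Lost regions were not confined to weak peaks. Their median score percentile was 56.0 and 59.1 in the wild-type lists, against 59.1 and 57.5 for kept regions, a mean difference of -0.735 ± 3.26 (SD, n = 2). Gained regions stood at median percentiles of 51.1 and 62.5 in the knockdown lists, against 63.9 and 68.8 for kept regions. The difference for lost regions was -5.38 without wild-type replicate 1 and -9.17 without wild-type replicate 2, where a lost region needs a peak in 1 wild-type list only.

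At the level of genes, HNRNPA2B1, an RNA-binding protein that acts in splicing, lost every listed peak, with 15 and 13 peaks in the wild-type lists. SMARCA4, the ATPase of the SWI/SNF remodelling complex, went from 13 and 11 to 0, and HK2, a hexokinase (8 and 10 peaks), and PDK1, a pyruvate dehydrogenase kinase (10 and 12), did likewise. Conversely, the remodeller genes CHD3 (10 and 10 peaks in knockdown) and RUVBL2 (8 and 5) and the signalling gene GSK3A (3 and 10) appeared only in the knockdown lists. Of 5607 genes with a peak in both wild-type lists, 719 (12.8%) were lost, and of 5612 in both knockdown lists, 960 (17.1%) were gained, while 3553 were kept. Among the 10992 genes with a peak in any list, independent lists would give 487 and 606, again without genes that no list held. Lost and gained genes summed to 1679, against 470 and 425 for the other splits.

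Unlisted numbers stood at the place of many genes that a list lacked. At places in the numbering that held 1 lost gene, an unlisted number stood in 56.6% of 256 places in knockdown replicate 1 and 66.2% of 320 in knockdown replicate 2. At places with 1 gained gene the shares were 50% of 328 and 55.9% of 363 in wild-type replicates 1 and 2. At places with 1 other gene that the list lacked and 2 lists held, the shares were 62.6 to 64.1%, so lost and gained genes did not stand out. Gained genes had the lower share in wild-type replicate 1 (Fisher's exact p = 0.00601), and no difference passed 0.05 in the other lists. Where no gene of another list was due, an unlisted number stood in 14.3 to 21.1% of places. Only 62 lost and 128 gained genes had no unlisted number in either list without them; HNRNPA2B1 had 22 and 19 and SMARCA4 19 and 18. Lost and gained therefore describe the lists, and where an unlisted number stands, the absence of a peak call is not shown. The gene counts also rest on single libraries: lost genes numbered 1308 and 1213 without wild-type replicates 1 and 2 and 1231 and 1542 without knockdown replicates 1 and 2, and gained genes 1615 without wild-type replicate 2 and 1818 and 1450 without knockdown replicates 1 and 2.

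Genes encoded in mitochondrial DNA were the group most often lost: 11 of the 15 with a peak in both wild-type lists (odds ratio 19, 95% interval 5.60 to 81.8, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted exact p = 2.53e-06). They were MT-CO1 and MT-CO3, which encode subunits of cytochrome c oxidase, MT-ND3, a subunit of complex I, and 8 tRNA genes, among them MT-TE, MT-TP, MT-TR and MT-TS1. Mitochondrial tRNA genes with a peak numbered 16 and 13 in the wild-type lists and 7 and 8 in the knockdown lists. Unlisted numbers stood at the place of 10 of the 11 lost genes in both knockdown lists. Only MT-TT was gained, of 5 members with a peak in both knockdown lists (adjusted exact p = 1). The odds ratio was lower without 1 library, between 8.83 (without wild-type replicate 2) and 14.3 (without knockdown replicate 1), and 6.04 in a logistic regression with score percentile and region number as covariates, each past the threshold. With genes of 1 region only it was 3.72 (adjusted exact p = 0.0621).

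Zinc finger protein genes were lost in 37 of 164 cases (odds ratio 2.03, 95% interval 1.36 to 2.98, adjusted exact p = 0.00519), led by ZNF483 with 13 and 7 wild-type peaks, ZNF486, ZNF680 and ZNF765. Noncoding RNA genes were lost in 8 of 22 cases (odds ratio 3.92, adjusted exact p = 0.0301), including GAS5, a host gene of small nucleolar RNAs with 13 and 11 peaks, and RNU11, a minor spliceosome RNA, and all 8 had unlisted numbers in both knockdown lists. That call ended without knockdown replicate 1 (odds ratio 2.47, adjusted exact p = 0.119), without knockdown replicate 2 (1.83, adjusted exact p = 0.208) and in the regression with covariates. Genes of p53 targets and apoptosis were lost in 7 of 20 cases (odds ratio 3.69, adjusted exact p = 0.0498), among them RRM2B (7 and 6 peaks), ZMAT3 (5 and 3) and XIAP (3 and 3). That call ended under 6 of 7 alternatives, among them leaving out each of the 4 libraries in turn, with odds ratios down to 1.81 and adjusted exact p up to 0.262. The remaining alternative, the replicate number as a block, repeats the main test by definition.

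The other 17 tested lists did not pass the threshold for loss. Histone genes lost 6 of 17 (odds ratio 3.73, adjusted exact p = 0.0648), with H1-4 and H2AC20 among them. They passed it without wild-type replicate 1 (odds ratio 3.33) and without wild-type replicate 2 (3.38). They did not pass it without knockdown replicate 1 (2.50), without knockdown replicate 2 (2.35) or with covariates (1.97). All 6 had unlisted numbers in both knockdown lists. Splicing genes lost 3 of 73, with HNRNPA2B1 and U2AF1 among them, a smaller share than other genes (odds ratio 0.288, adjusted exact p = 0.0732). They passed the threshold without wild-type replicate 1 (0.368), wild-type replicate 2 (0.315) or knockdown replicate 2 (0.233), but not without knockdown replicate 1 (0.768). Among RNA modification enzymes, 4 of 24 were lost: NAT10, RBM15 and WTAP, both of the m6A writer complex, and NSUN2, an RNA cytosine methyltransferase. The pluripotency list lost DNMT3B and PRDM14, 2 of 33. Ribosomal protein genes lost 8 of 55, with RPL29, RPL34, RPS25 and RPL9 leading, and translation factors lost 4 of 49, of which EEF1A1P11 and EIF4BP7 are pseudogenes. Losses came to 1 of 24 histone chaperones (DNAJC9), 1 of 27 Polycomb and COMPASS genes (WDR5), 1 of 39 remodellers (SMARCA4), 3 of 42 histone-modifying enzymes, 3 of 60 ribosome biogenesis genes, 2 of 47 oxidative phosphorylation genes (ATP5MG and ATP5ME) and 2 of 18 glycolysis genes. They came to 5 of 68 cell cycle genes, with CDK1, ORC3, RB1 and RPA1 leading, 3 of 64 chaperone and proteasome genes, 4 of 48 signalling genes and 1 of 46 cytoskeleton and matrix genes (COL4A5). Lineage markers had too few members to test: 0 of 3 ectoderm, 0 of 3 mesoderm, 0 of 2 trophectoderm and no endoderm genes were lost. Without wild-type replicate 1, 10 lists passed the threshold in place of 4, and without wild-type replicate 2, 8 did; remodellers passed it, with fewer losses than other genes, without each of the 4 libraries in turn (odds ratios 0.107 to 0.218). Oxidative phosphorylation genes did so with score percentile and region number as covariates (0.182, against 0.300 without).

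**Figure D3:**
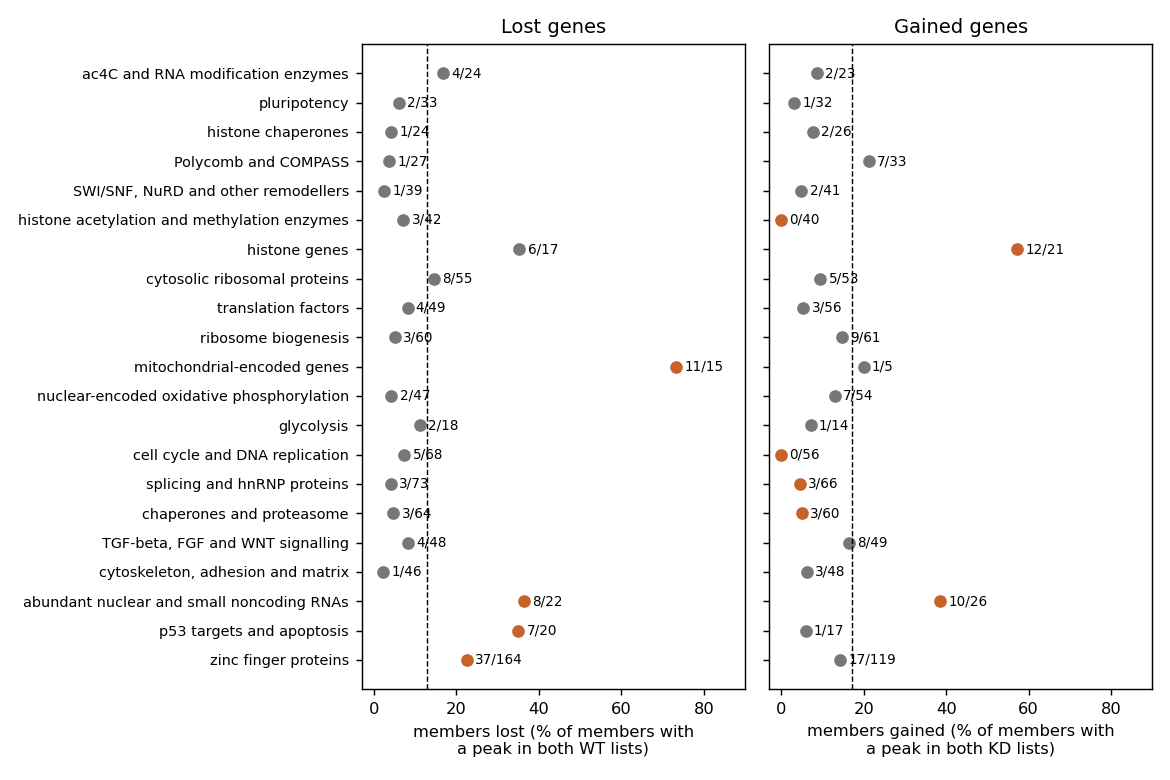
Percent of each gene list's members that were lost (left, of members with a peak in both wild-type lists) or gained (right, of members with a peak in both knockdown lists), with the counts beside each point. Orange points passed an adjusted p of 0.05 by Fisher's exact test, grey points did not, and dashed lines mark the share over all genes, 12.8% lost and 17.1% gained; mitochondrial-encoded genes lead the lost side with 11 of 15 and histone genes the gained side with 12 of 21.

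Histone genes were the group most often gained: 12 of 21 with a peak in both knockdown lists had 0 peaks in either wild-type list (odds ratio 6.53, 95% interval 2.52 to 17.6, Fisher's exact test, adjusted exact p = 0.000466). They were H1-6, H2AC15, H2BC4, H2BC6, H2BC13, H2BC14, H2BC21, H2BU1, H3C1, H4-16, H4C5 and H4C15, most of them genes of the replication-dependent clusters. Unlisted numbers stood at 7 of the 12 in both wild-type lists and at none for 2 of them. Noncoding RNA genes were gained in 10 of 26 cases (odds ratio 3.05, adjusted exact p = 0.0311), led by RNVU1-22, a variant U1 small nuclear RNA, and SNORD116-11, so this list was enriched among lost and gained genes alike. The odds ratio of histone genes fell to between 3.63 (without knockdown replicate 1) and 4.08 (without knockdown replicate 2) when 1 library was left out, each past the threshold, and with genes of 1 region only the adjusted exact p was 0.0729 for histone and for noncoding RNA genes. The call for noncoding RNA genes also ended without wild-type replicate 1 (adjusted exact p = 0.0543), without wild-type replicate 2 (0.143) and in the regression with covariates, and their odds ratio was 4.95 without knockdown replicate 2.

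Cell cycle and histone-modifying genes were absent from the gained genes. Of those with a peak in both knockdown lists, 0 of 56 cell cycle genes (adjusted exact p = 0.000466) and 0 of 40 histone acetylation and methylation enzymes (adjusted exact p = 0.00721) were gained. Splicing genes gained 3 of 66 (odds ratio 0.228, adjusted exact p = 0.0233), among them HNRNPK and SNRPD3, and chaperone and proteasome genes 3 of 60 (odds ratio 0.253, adjusted exact p = 0.0311), with HSPA8 and PSMB10 leading. The call for histone-modifying enzymes ended without knockdown replicate 1 (adjusted exact p = 0.136). Those for splicing and chaperones ended in the regression with covariates.

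The remaining lists did not pass the threshold for gain. RNA modification enzymes gained 2 of 23, PUS1, a pseudouridine synthase, and NSUN5, and pluripotency genes 1 of 32, NODAL, a TGF-beta family ligand (adjusted exact p = 0.0836). Polycomb and COMPASS genes gained 7 of 33, with L3MBTL2 and MEN1 leading, remodellers 2 of 41, histone chaperones 2 of 26 (NAP1L1 and TONSL), ribosomal protein genes 5 of 53, with RPL5 and RPL26L1 leading, and translation factors 3 of 56 (adjusted exact p = 0.0559), among them EIF3G. Ribosome biogenesis genes gained 9 of 61, with NOP10 and GAR1 leading, oxidative phosphorylation genes 7 of 54, with UQCRQ and COX5B leading, glycolysis genes 1 of 14 (ALDOC), signalling genes 8 of 49, with GSK3A and RPTOR leading, and cytoskeleton and matrix genes 3 of 48, with KRT19 and HSPG2 leading. Genes of p53 targets and apoptosis gained 1 of 17 (TP53I3), and zinc finger genes 17 of 119, with ZNF687 and ZNF425 leading. Among lineage markers, SOX3 was gained of 4 ectoderm genes, TNNT2 of 3 mesoderm genes, KRT19 of 2 endoderm genes and 0 of 3 trophectoderm genes. Without knockdown replicate 1, 11 lists passed in place of 6. With fewer gains than other genes, pluripotency genes passed without wild-type replicate 2 and without either knockdown library (odds ratios 0.121 to 0.189), as did translation factors with equal list lengths and without either knockdown library (0.190 to 0.241). Remodellers did so with equal list lengths (0.219), without wild-type replicate 1 (0.152) and without knockdown replicate 1 (0.237), but not without wild-type replicate 2 (0.422).

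Chaperone, pluripotency and cell cycle genes were kept in all 4 lists more often than other genes, with and without score percentile and number of regions as covariates. Chaperone and proteasome genes were kept in 52 of 78 cases (odds ratio 4.23, adjusted exact p = 1.18e-08, and 3.76 with covariates) and cell cycle genes in 50 of 84 (3.11, adjusted exact p = 1.9e-06, and 2.24 with covariates). Pluripotency genes were kept in 27 of 45 (3.16, adjusted exact p = 0.00037, and 3.44 with covariates), among them DPPA4 (14 and 13 against 10 and 11 peaks) and L1TD1 (4 and 8 against 7 and 3). Remodellers were kept in 35 of 50 (4.92, adjusted exact p = 3.1e-07), with HDAC2 and PHF10 leading, and splicing genes in 57 of 93 (3.35, adjusted exact p = 1.11e-07), with HNRNPH1 and DDX5 leading. RNA modification enzymes were kept in 18 of 30 (3.15, adjusted exact p = 0.00422), among them DKC1, the pseudouridine synthase of box H/ACA particles, with 13 and 10 wild-type and 7 and 12 knockdown peaks. With covariates the odds ratios of these lists were 1.21, 1.58 and 1.08, and none passed the threshold. The number of regions was counted over the same 4 lists that define kept genes. It therefore holds part of the outcome, and the model cannot separate the group from it. Kept shares above those of other genes were also found for cytoskeleton and matrix genes (39 of 58), histone-modifying enzymes (35 of 55, odds ratio 3.69, and 1.93 with covariates), histone chaperones (21 of 33), translation factors (40 of 72), ribosome biogenesis (44 of 81), signalling (38 of 73) and Polycomb and COMPASS genes (22 of 43, adjusted exact p = 0.0189).

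Zinc finger genes (78 of 356 kept, odds ratio 0.578, adjusted exact p = 4.69e-05), noncoding RNA genes (12 of 79, 0.373), histone genes (8 of 47, 0.428, adjusted exact p = 0.0374) and mitochondrial genes (2 of 25, 0.182, adjusted exact p = 0.0133) were kept less often than other genes. Ribosomal protein genes (36 of 85), oxidative phosphorylation genes (33 of 77), glycolysis genes (13 of 25), p53 and apoptosis genes (11 of 33), ectoderm (3 of 7) and mesoderm markers (2 of 5) did not differ past the threshold, and endoderm (0 of 3) and trophectoderm markers (2 of 4) were too few to test. With score percentile and number of regions together as covariates, 4 lists in place of 17 passed, namely chaperones, pluripotency, cell cycle and oxidative phosphorylation, and the odds ratio turned above 1 for histone (2.71), mitochondrial (5.76) and noncoding RNA genes (1.18) and below 1 for Polycomb and COMPASS genes (0.857). As the number of regions holds part of the outcome, these changes decide nothing about the groups. The call for Polycomb and COMPASS genes also ended without wild-type replicate 2 (adjusted exact p = 0.0702) and without knockdown replicate 1 (0.157).

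Knockdown peaks lay more often on chromosome 19, which is dense in genes. It held 3.56 and 3.95% of the peaks in the wild-type lists and 7.35 and 8.03% in the knockdown lists, a ratio of 2.05, and it held 25 lost, 146 gained and 177 kept genes. Chromosomes 22 (ratio 1.53), 20 (1.34), 16 (1.33), 17 (1.23) and 11 (1.2) also had larger shares in knockdown, and chromosomes 18 (0.691), 4 (0.698), 13 (0.766), 10 (0.780) and 2 (0.799) smaller ones. Genes with a peak were shorter in knockdown, with a median genomic span of 33.5 and 30.9 kb against 42.0 and 39.9 kb in wild type (ratio 0.788). Gained genes had a median span of 15.7 kb (949 genes), against 45.7 kb for lost (708) and 44.1 kb for kept genes (3549), a difference of -1.54 from lost and -1.49 from kept genes on the log2 scale (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Lost and kept genes differed by 0.05 (permutation p = 0.478). These tests shuffled genes, which are not replicates, and so describe these lists only.

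Peaks also lay nearer to gene starts in knockdown. The first 10% of the gene span held 6.67 and 8.98% of peaks in wild type and 11.8 and 11.3% in knockdown (ratio 1.47), and the last 10% held 30.5 and 29.0% against 23.7 and 25.5% (ratio 0.827). Of gained regions 17.4% lay in the first 10%, against 6.97% of lost and 11% of kept ones. For the chromosome 19 share, the gene span and both ends of genes, both knockdown libraries stood on the same side of both wild-type libraries (exact permutation p = 0.333, the smallest possible). These measures were chosen after the data were seen.

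**Figure D4:**
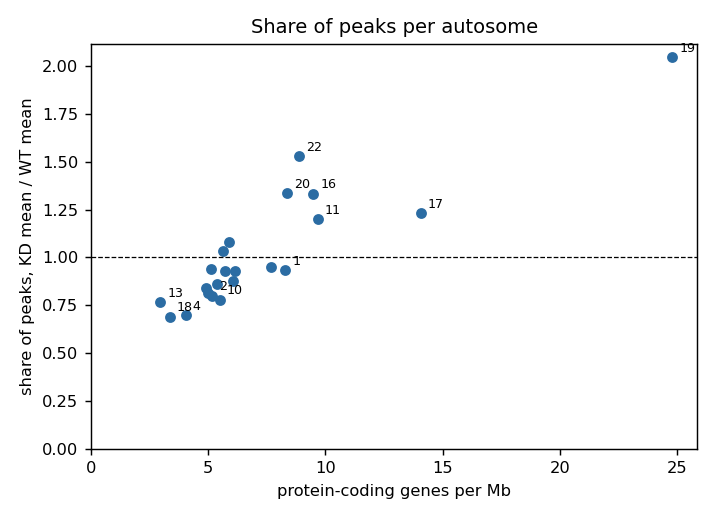
Share of peaks on each of the 22 autosomes in knockdown over wild type (ratio of means of 2 libraries each, vertical axis) against protein-coding genes per Mb (horizontal axis); each point is a chromosome and the dashed line marks a ratio of 1. Chromosome 19 stands at 2.05, chromosome 22 at 1.53 and chromosome 18 at 0.691.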

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

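Chosen only after the data were seen were the settings with spans up to 1000 nt, merging within genes and no unlisted number, and every setting of the chromosome 19 share, gene span and position along genes and, for overlap and peak strength, those without 1 library. Of 151 alternative values of the 16 main results, 114 counted as unchanged, 35 moved further and 2 reversed. Counts had to stay within 1.5 times, and overlap and peak strength within their spread. Ratios of knockdown over wild type had only to stay on the same side of 1. Of 484 values of single gene lists and sets of named genes, 386 kept their direction and side of the threshold, 32 were no longer past it, 39 came to pass it and 27 reversed. The replicate number as a block repeats the main gene counts and list tests by definition, and its values are among the unchanged ones. All values of the chromosome 19 share, gene span and position along genes stayed within these bounds.

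The stronger 50% of each list gave 3260 lost, 3226 gained and 926 kept regions, and the stronger 50% on 1 side only gave 2647 lost and 2343 gained regions and 624 gained genes; fewer peaks enter by construction. Spans up to 1000 nt gave 1310 kept regions. Requiring no unlisted number left 2441 lost and 1935 gained regions and 62 lost and 128 gained genes. Leaving out 1 library widened the classes, since a class then needs a peak, or its absence, in 1 list of that genotype only. Lost regions ran from 7912 to 26024, gained regions from 7502 to 23202, kept regions from 4126 to 4783, lost genes from 1213 to 1542 and gained genes from 1404 to 1818; the libraries and values behind changes of over 1.5 times stand beside these counts in the results. The peak strength of lost regions ran from -9.17 (without wild-type replicate 2) to -0.407 (without knockdown replicate 2).

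The knockdown over wild-type ratio was 1.04 for genes with a peak and 1.07 for covered length, on the other side of 1 from the ratio for peaks; the cause was not tested. The excess of overlap within genotypes was 10.6 percentage points for shared genes, against 16.1 for peaks.

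Past the threshold for lost genes stood 1 list with genes of exactly 1 region and 4 to 10 without 1 library (10 without wild-type replicate 1, 8 without wild-type replicate 2). For gained genes it was 0 lists with 1 region, 3 with covariates, and 6 to 11 without 1 library (11 without knockdown replicate 1). For kept genes it was 0 with 1 region and 4 with covariates, where the number of regions holds part of the outcome. Few genes have 1 region, so that setting tests little, and for lost noncoding RNA genes it gave no finite odds ratio. Odds ratios of kept genes turned to the other side of 1 for histone genes (2.36 with 1 region, 2.71 with covariates), mitochondrial genes (4.56 and 5.76), Polycomb and COMPASS genes (0.857 with covariates) and noncoding RNA genes (1.18 with covariates); the cause was not tested. The other odds ratios that crossed 1 were past the threshold neither in the report nor where they crossed. Among lost genes they were those of ribosomal proteins (0.871 with equal lengths, 0.808 with covariates, 0.659 to 1.22 without 1 library), RNA modification enzymes (0.693 to 1.07) and glycolysis (0.514 to 1.02). Among gained genes they were those of mitochondrial genes (0.203 with 1 region, 0.735 with covariates, 0.475 to 2.00 without 1 library), Polycomb and COMPASS (0.912 to 1.08), ribosome biogenesis (0.482 to 1.07), oxidative phosphorylation (0.386 to 1.15, where 0.386, without knockdown replicate 1, passed the threshold) and zinc finger genes (0.794 to 1.04). Among kept genes they were those of mesoderm markers (0.933 to 1.07) and p53 and apoptosis genes (0.781 to 1.16), again without 1 library.

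Replicate numbers did not pair the libraries: lists of different genotypes shared 23.8% of peaks with the same number and 23.9% with different numbers, a difference of -0.0314. With the replicate number as a block there were 7109 lost, 6298 gained and 2721 kept regions, and the overlap excess was 16.2. Genes gave 719, 960 and 3553 again, and 4, 6 and 17 lists passed again. The definition fixes both, so this setting tests nothing for genes and gene lists.

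A stricter overlap, a 200 nt gap and strand cannot change gene counts and gave no value there. Other settings for peak location, base composition and a further score column were not run, as no exon annotation, genome sequence or further score was used here. Read depth is unknown, so a missing peak cannot be told from a shallow library.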

Other observations

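The comparison of peak density between genes and, among the tests below, those of unlisted numbers at lost and gained genes, of weak peaks at gained regions, of unlisted numbers at mitochondrial genes, of different genes at gene starts, of long spans, of gene density and of peak strength at mitochondrial genes were chosen only after the result was seen.

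Genes that held peaks in every list differed in how many they held. Among 1983 genes with a peak in all 4 lists and at least 20 peaks over them, counted as peaks per 10000 of the list, 156 were lower in knockdown and 89 higher, with every library of one genotype more than 2 times every library of the other, a sum of 245 against 11 and 12 for the other splits of the lists. The genes named here were chosen after their values were seen. Those with the most peaks among the lower ones were MACF1, a cytoskeletal linker, with 80 and 66 peaks in wild type against 17 and 25 (log2 difference -1.56), DST, another linker, with 52 and 50 against 7 and 4 (-2.89), PRKDC, a DNA repair kinase, with 56 and 34 against 6 and 16 (-1.85), USP9X, a deubiquitinase, with 31 and 33 against 10 and 6 (-1.68), and 1 gene identifier of the noncoding SNHG14, with 36 and 29 against 7 and 7 (-1.94), while its other identifier had 89 and 86 against 38 and 52 and was not among the lower ones.

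On the opposite side, SRCAP, a chromatin remodeller, had 6 and 6 peaks in wild type against 27 and 30 in knockdown (2.51), and KMT2D, a histone H3 lysine methyltransferase, 3 and 8 against 22 and 26 (2.38). Its paralogue KMT2C went the other way, with 32 and 17 peaks against 5 and 5 (-2.02). NUP214, a nuclear pore protein, had 6 and 9 against 23 and 34 (2.16), SPG7, a mitochondrial protease, 2 and 4 against 15 and 21 (2.82), and AUTS2 6 and 2 against 19 and 19 (2.52). Chromosome 19 held 15 of the 89 genes higher in knockdown and 1 of the 156 lower ones.

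Genes and regions with peaks in both lists of 1 genotype and in neither of the other were set against numbers left out of the lists and against weak peaks. At places of the numbering with 1 such gene, the share with an unlisted number differed by -12.6 to 2.11 percentage points over the 4 lists from that at other genes the list lacked. Such genes therefore did not stand out above other absent genes. The share itself, 50 to 66.2%, lay above the 14.3 to 21.1% of places where no gene of another list was due. Unlisted numbers thus stood in excess at these genes, and how many of the lost and gained genes they account for stays open. As the whole cause of lost and gained regions, peaks left out of the lists were argued against. Where no unlisted number stood, the split by genotype held 3.34 times as many regions as the larger other split. For weak peaks, the share among the stronger 50% of peaks was 0.924 of that over all peaks for lost and 0.861 for gained regions. This argues against the weaker 50% of peaks as the whole cause. The stronger 50% began at median scores of 12.7 to 13.8, near the lowest score of 10, so the cut cannot exclude peaks near the limit. Gained regions also stood at lower median percentiles than kept ones in the knockdown lists (51.1 and 62.5 against 63.9 and 68.8). For gained genes the share fell from 17.1 to 13.8% and for lost genes from 12.8 to 11.5%. A loss of acetylation after NAT10 knockdown, a change in the amount of RNA and a difference between library preparations stay open, as input libraries were not analysed here. An effect of transduction, GFP enrichment or puromycin stays open too, since the labels give these for the knockdown cells only.

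The larger share of knockdown peaks on chromosome 19, in short genes and near gene starts was set against 3 explanations. Different genes in the lists, as the whole cause, were argued against for chromosome 19 and gene starts, though not for short genes. Among genes with a peak in all 4 lists the chromosome 19 share was still 1.63 times as high in knockdown, against 2.05 over all peaks. A part from different genes therefore stays open there. In the first 10% of the gene the share was 1.51 times as high among these genes, against 1.47 over all peaks. Long spans across introns, as the whole cause, were argued against for chromosome 19, with a ratio of 1.87 for spans up to 1000 nt. Over the 22 autosomes the ratio of shares rose with the density of protein-coding genes (Spearman's rho 0.876, permutation p = 1e-05, the smallest that 100000 permutations can give), which a bias of libraries with base composition and a change in the amounts of RNA could both produce. These cannot be told apart without sequence and input libraries, and either remains a hypothesis; chromosomes are not independent replicates.

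Mitochondrial genes with peaks in both wild-type lists and in neither knockdown list could be genes whose knockdown peaks were numbered and left out. Unlisted numbers stood at the place of 10 of these 11 genes in both knockdown lists, against 63.8% of the other lost genes (Fisher's exact p = 0.108), and the places of 5 of the 10 held that gene alone in both lists while the others held up to 8, so this stays open. Weak peaks were argued against, since the median of the lower wild-type percentile was 98.6. Lower acetylation or lower amounts of these RNAs in knockdown cells were not tested and stay open.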
